A study of Caenorhabditis elegans with 8 samples.

How the data were processed

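Polyadenylated RNA of Caenorhabditis elegans was sequenced in 8 libraries, 2 each from sperm, oocytes and embryos of the 1-cell and 2-cell stages, and all libraries were used. The deposited table holds RPKM values made by the authors for 21774 genes. The labels name the aligner BWA without a version. The genome build, the gene annotation, the counting tool and the reads used as the total were not stated, so no positions are given. No raw counts, stated depths or sequencing batches were given, and no counting intervals were computed. Depths inferred for the embryo and sperm libraries served only for a rough simulation of counting error. Low values of a gene kept common ratios between the embryo and sperm libraries, as whole reads over a single gene length would give. The oocyte columns showed few such ratios and far fewer zeros, and the labels do not say why. If these columns were made in another way, that difference enters every comparison with oocytes, the small SD between oocyte libraries and the trend with transcript length.

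Samples were grouped by their titles. The labels give 1 strain (TX189, OMA-1::GFP) and a temperature of 24 degrees for all libraries. The protocol, which names wild-type N2 hermaphrodites for the hand-picked oocytes and a fog-2(q71) background for the males, differs from that label, so strain and collection method cannot be separated from stage. The protocol as given describes the sorting of 1-cell embryos only. Replicate numbers give 2 same-numbered pairs per comparison, and nothing says that the pairs share a culture or a day.

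Gene names of the table were matched to a current annotation (WBcel235), which found 18746 and left 3028 without a match (947 of these among the genes tested). Transcript length was the longest annotated transcript. Genes with at least 1 RPKM in at least 2 of the 8 libraries were tested, which left 11935. RPKM were used as deposited, with a pseudocount of 1 before the log2.

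Differences between groups were tested with limma 3.58.1 in R 4.3.3. A one-way model of all 4 groups was fitted with a variance trend on 4 residual degrees of freedom, and limma's moderated test was two-sided. Benjamini-Hochberg adjustment was made within each of the 4 comparisons: 1-cell embryo against oocyte, 2-cell against 1-cell embryo, 2-cell embryo against oocyte, and sperm against oocyte. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. On simulated data without a length trend this test recovered 27.5%, 62.3% and 95.3% of changes of 1.5, 2 and 3 log2, and 4.88% of its calls were false. This simulation, like that of the length removal below, gave each gene independent noise of equal spread in all libraries and changed 200 genes. The real libraries differed in spread between groups, and same-numbered embryo libraries deviated together, so these rates need not hold for them.

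Before the data were examined, 24 gene lists were written, with the comparisons, tests and alternatives. They were major sperm proteins; spermatogenesis and sperm function; maternal RNA-binding regulators; eggshell, fertilization and egg activation; embryonic polarity and early cell fate; cell cycle, centrosome and spindle; early zygotic transcripts; P granule and germline determinants; and meiotic chromosomes. Others covered Argonautes and small RNA pathways, mRNA decay, translation factors, ribosomal proteins, proteasome subunits, histones, heat shock, the nuclear-encoded respiratory chain and the mitochondrial genome. Markers of other tissues were listed for yolk, intestine, body wall muscle, somatic gonad, cuticle and neurons. The sperm lists and the early zygotic list were also set down as markers of other cells in the samples, the last for older embryos. No mitochondrial genome mRNA was found in the table, and that list has no result. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over all lists and comparisons. No list call held with an estimated correlation, which was run on the values as deposited and not with the length trend removed.

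Genes were named by a rule: the 10 called genes with the largest change in each direction that had a mean of at least 10 RPKM in the higher group and no overlap between libraries. To these were added up to 4 called members of each list (or 2 where none was called) by mean RPKM, and a panel of 25 genes. Some were left out for space, and the panel gene peel-1 was not in the table.

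The set of sperm-enriched transcripts had at least 10 RPKM in both sperm libraries and at least 10-fold more than in oocyte replicate 1. It was measured against oocyte replicate 2, so that choosing low oocyte values did not itself give a rise, and compared with 10000 random lists of equal size matched on oocyte level. These lists were drawn from all genes of the table outside the set, including genes too low to be tested. On simulated null lists 4.5% fell outside the central range of this comparison.

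Alternatives chosen before any value was seen were pseudocounts of 0.1 and 5, no filter or a filter of 5 RPKM, scaling to a common sum, median-of-ratios scaling, quantile normalization, only the compared groups, no variance trend, a replicate block, and leaving out each library. Added after seeing the data were replicate blocks limited to some groups, the calls shared by all scalings, the removal of each library's trend on transcript length by loess (10988 genes with a length), and some subsets. That trend was fitted together with each gene's mean level over all 8 libraries. Genes far higher in sperm were therefore corrected at a level above their own in oocytes and embryos. The length removal was tested on simulated data with a slope of -0.34 over all unchanged genes and a trend that faded at low levels. The -0.62 measured was fitted only on genes with a mean of at least 10 RPKM, so these slopes are not comparable. With the simulated trend 111.2 unchanged genes were called as simulated, beside 200 genes that were changed, and 15.2 after the removal. It brought the slope to -0.06 while recovering 96.2% of changes of 3 log2 against 95.8% without it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.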

Results

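Polyadenylated RNA was measured by sequencing in the nematode Caenorhabditis elegans. The samples were oocytes, sperm, and embryos at the 1-cell and at the 2-cell stage, with 2 libraries in each of the 4 groups. The series set out to follow the oocyte-to-embryo transition, the time in which the fertilized egg runs on maternal transcripts before its own genome is switched on. Values are the RPKM deposited by the authors for 21774 genes, and the table gives no counts or depths. The commonest product of RPKM and transcript length among low genes, taken as 1 read, gave rough depths of 2.07e+07 and 3.51e+07 reads for the 1-cell, 1.76e+07 and 2.99e+07 for the 2-cell and 2.02e+07 and 7.0e+07 for the sperm libraries, while the depth of the oocyte libraries is unknown. The RPKM of a library summed to 679187 and 642169 in oocytes, 866028 and 923528 in 1-cell embryos, 832603 and 862903 in 2-cell embryos, and 954484 and 1.01351e+06 in sperm. Values of 0 made up 2.48% and 2.93% of genes in the oocyte libraries, 26.4% to 29.4% in the embryo libraries, and 18.8% and 12.7% in the sperm libraries, and what set this difference is not stated. Fold changes are differences of log2(RPKM + 1), a scale that understates changes of genes near 0.

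Replicates of the oocyte lay closest together. The median SD between replicates was 0.09 log2 in oocytes, 0.31 in 1-cell embryos, 0.29 in 2-cell embryos and 0.41 in sperm. Across genes, which are not independent replicates, Pearson's r between the replicates was 0.995 in oocytes, 0.963 in 1-cell embryos and 0.930 in sperm. The 1-cell and 2-cell libraries that carry the same replicate number lay closer to each other (r = 0.995 for number 1 and 0.993 for number 2) than the replicates of the 1-cell stage did. Nothing in the labels says whether replicates were separate cultures, so the p-values measure the spread between libraries only. Stage was also confounded with collection: oocytes were picked by hand from dissected wild-type hermaphrodites, 1-cell embryos were sorted by flow cytometry, and sperm was purified from males of a fog-2 mutant background. How 2-cell embryos were collected is not described.

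The change from oocyte to embryo depended on the length of the transcript. Among 6643 genes with a mean of at least 10 RPKM, the log2 difference between 1-cell embryos and oocytes had a slope of -0.62 per doubling of annotated transcript length (Pearson's r across genes -0.465). Its median was 1.43 for the 494 genes of up to 500 nucleotides, 1.27 for 1591 genes from there to 1000 nucleotides, 0.45 for 2803 genes from there to 2000 nucleotides, -0.17 for 1470 genes from there to 4000 nucleotides, and -0.21 for 285 longer genes. Slopes between replicates were smaller (-0.11 in oocytes, 0.09 in 1-cell embryos, 0.02 in 2-cell embryos and 0.16 in sperm), as was the slope between 2-cell and 1-cell embryos (0.10). That last difference still followed length across genes, in the opposite direction (Pearson's r 0.364). The slope was -0.52 between 2-cell embryos and oocytes and -0.70 between sperm and oocytes, the latter with a Spearman's rho across genes of -0.0460. Gene groups are therefore given with their test after this trend was removed wherever that ended a call.

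**Figure D1:**
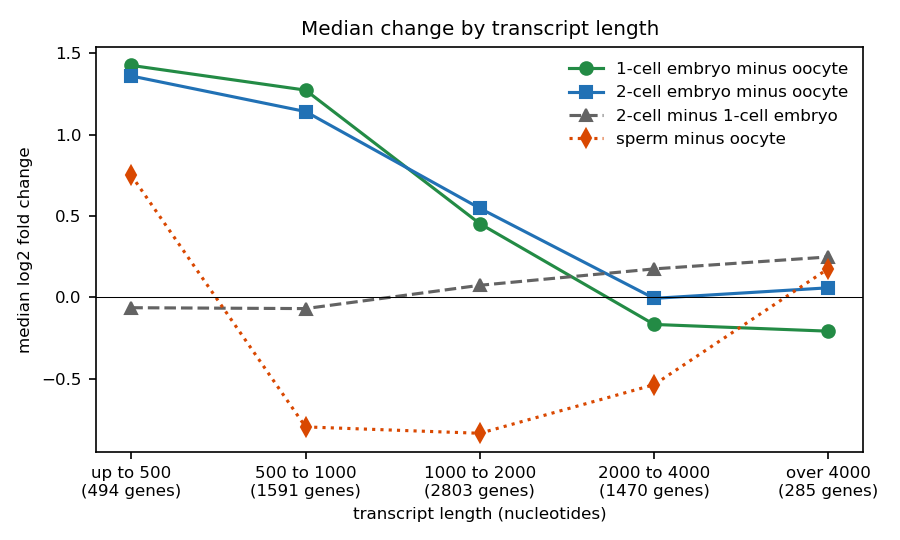
Median log2 fold change of genes with a mean of at least 10 RPKM (vertical axis) in 5 classes of annotated transcript length in nucleotides (horizontal axis), with 1 line per comparison. The medians of 1-cell embryos minus oocytes ran from 1.43 in the class of the shortest transcripts to -0.21 in that of the longest, and those of 2-cell minus 1-cell embryos from -0.06 to 0.25.

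The comparison of 1-cell embryos with oocytes asks which maternal transcripts are lost, and which appear, around fertilization. Transcripts for the eggshell and for sperm reception fell. The chondroitin proteoglycan cpg-2 (B0280.5), which forms part of the eggshell, dropped from 7365 ± 701 RPKM (mean ± SD, n = 2) in oocytes to 655 ± 49.2 in 1-cell embryos, a log2 change of -3.49 (SE 0.70, adjusted p = 0.0150). The sperm-binding receptor gene egg-1 (B0244.8) had a log2 change of -4.32, the yolk receptor rme-2 (T11F8.3) of -4.18 and the eggshell proteoglycan cpg-1 (C07G2.1) of -3.77. The log2 change was -3.0 for the chitin-binding cbd-1 (H02I12.1), -2.19 for the chitin synthase chs-1 (T25G3.2) and -1.61 for the egg activation kinase mbk-2 (F49E11.1). Of the 18 tested genes for eggshell, fertilization and egg activation, 8 were lower and 1 was higher (12 and 2 adjusted over the list alone), and the higher one was spe-11, a factor supplied by sperm. The list as a whole was lower than other genes (adjusted p = 3.3e-07, but adjusted p = 0.847 with an estimated correlation). With the length trend removed the list stayed lower (adjusted p = 4.28e-05), with 3 members called lower. The calls of cpg-1 (-2.13), cpg-2 (-1.96), cbd-1 (-0.62), chs-1 (-0.90) and mbk-2 (-0.01) ended there, and those of egg-1 and rme-2 did not. The call of egg-1 ended without the filter on low values.

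RNA-binding proteins that control maternal messages formed the next group that fell. The level of lin-41 (C12C8.3), a regulator of oocyte maturation, went from 213 ± 75.3 to 11.5 ± 0.91 RPKM (log2 -4.05, SE 0.47, adjusted p = 0.00629). The mean of mex-3 (F53G12.5), a KH-domain regulator of embryonic fate, was 1054 ± 66.8 RPKM in oocytes and 147 ± 6.98 in 1-cell embryos (log2 -2.83). The log2 change was -3.02 for car-1 (Y18D10A.17), -2.92 for puf-3 (Y45F10A.2), -2.67 for both gld-1 (T23G11.3) and cgh-1 (C07H6.5), -2.37 for mex-5 (W02A2.7) and -1.47 for oma-1 (C09G9.6). For oma-1 the strain is in doubt, since the labels name an OMA-1::GFP strain for all libraries and the protocol wild-type worms for the oocytes. Of 30 tested regulators, 14 were lower and 0 higher, with the same counts adjusted over the list alone (list test adjusted p = 4.16e-10, and adjusted p = 0.847 with an estimated correlation). Other members did not pass the test: puf-5 (F54C9.8; log2 -1.42, adjusted p = 0.228), oma-2 (ZC513.6; -1.21, 0.325), pie-1 (Y49E10.14; -1.08, 0.230), spn-4 (ZC404.8; -0.64, 0.501), pos-1 (F52E1.1; 0.67, 0.591) and nos-2 (ZK1127.1; 1.39, 0.161). With the length trend removed the list stayed lower (adjusted p = 1.17e-04), with 4 members lower and 1 higher. lin-41 and car-1 kept their calls while those of mex-3 (-1.63), puf-3 (-2.05), gld-1 (-1.29), cgh-1 (-1.06), mex-5 (-0.75) and oma-1 (-0.45) ended. The call of puf-3 also ended with quantile normalization.

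**Figure D2:**
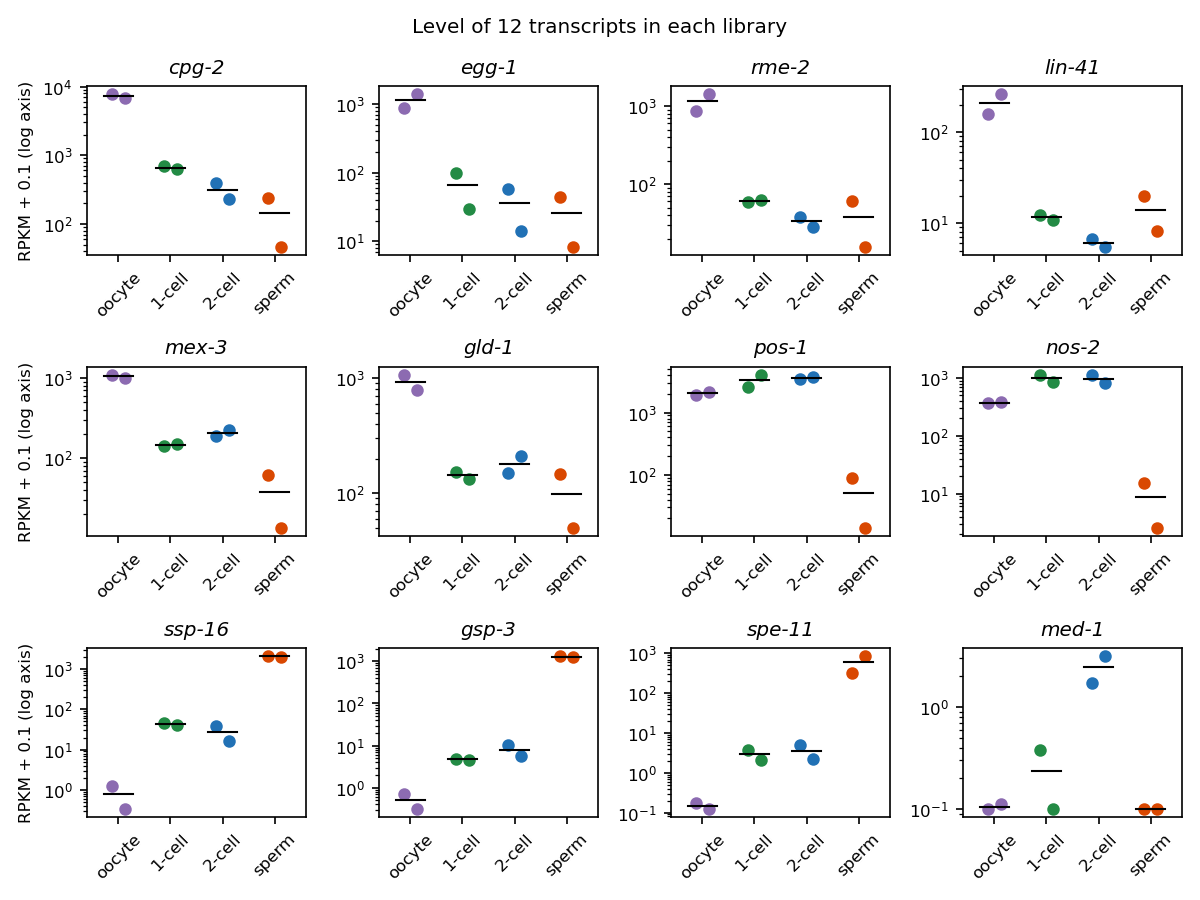
RPKM + 0.1 (vertical, log axis) of 12 transcripts in the 4 groups (horizontal axis), with a point for each library and a bar at the mean of the 2 libraries. The eggshell gene cpg-2 had a mean of 7365 RPKM in oocytes, 655 in 1-cell embryos and 315 in 2-cell embryos, while pos-1 had 2025, 3304 and 3623 RPKM in the same groups, a difference that did not pass the test.

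gfat-2, pygl-1, tsn-1, gfat-1 and acly-1 were among the 10 named genes with the largest decreases. gfat-2 (F22B3.4) and gfat-1 (F07A11.2), which make the amino sugar that feeds chitin synthesis, had log2 changes of -6.69 and -5.06. For gfat-2 the mean was 860.0 ± 317 RPKM in oocytes and 7.41 ± 3.45 in 1-cell embryos. The glycogen phosphorylase pygl-1 (T22F3.3) went from 1743 ± 103 to 16.7 ± 3.64 RPKM (log2 -6.63, SE 0.37, adjusted p = 0.00165). The Tudor-domain nuclease homolog tsn-1 (F10G7.2) had a log2 change of -6.42, and the ATP citrate lyase acly-1 (D1005.1) of -4.53. These 5 genes kept their calls under each scaling tried and with the length trend removed.

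Further maternal groups were lower as lists at this step: polarity, P granule, cell cycle and proteasome genes. The call of the polarity list stayed with the length trend removed, with 3 members then called higher and 4 lower, and those of the other lists ended (2 higher and 1 lower of the P granule, 8 and 4 of the cell cycle and 1 and 1 of the proteasome genes). Among 30 polarity and early cell fate genes, 6 were lower and 0 higher (9 and 0 adjusted over the list alone), among them the kinase gsk-3 (Y18D10A.5; 91.0 ± 8.66 to 5.15 ± 3.70 RPKM, log2 -4.04), the cortical polarity gene par-2 (F58B6.3; -2.67) and the G protein genes gpa-16 (Y95B8A.5; -2.67) and goa-1 (C26C6.2; -2.01). The list had an adjusted p of 3.68e-06 (adjusted p = 0.847 with an estimated correlation) and of 0.0225 with the length trend removed, while the Notch receptor glp-1 (F02A9.6) had a log2 difference of 0.57 (adjusted p = 0.493). Of 18 P granule genes, 3 were lower, with the same count adjusted over the list alone: pgl-3 (C18G1.4; -3.45), glh-2 (C55B7.1; -1.68) and gap-3 (Y20F4.3; -2.62). That list had an adjusted p of 1.74e-04 (adjusted p = 0.847 with an estimated correlation) and of 0.258 with the length trend removed. Of 54 cell cycle, centrosome and spindle genes, 6 were lower and 3 higher (5 and 2 adjusted over the list alone), including the ubiquitin ligase subunit cul-3 (Y108G3AL.1; -2.69), the kinesin klp-7 (K11D9.1; -3.09) and, higher, the chromosomal passenger gene bir-1 (T27F2.3; 2.02). Its adjusted p was 0.00205 (adjusted p = 0.847 with an estimated correlation) and 0.825 with the length trend removed, and the cyclin cyb-1 (ZC168.4) had a log2 difference of -0.55 (adjusted p = 0.329). Of 32 proteasome subunits, 3 were lower (3 adjusted over the list alone), including rpn-1 (T22D1.9; -1.77) and rpt-6 (Y49E10.1; -1.75), with an adjusted p of 0.0253 (adjusted p = 0.900 with an estimated correlation) and of 0.932 in the other direction with the length trend removed. In these 4 lists the calls of gpa-16, goa-1, glh-2, gap-3 and rpn-1 ended with the length trend removed.

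Heat shock and cuticle lists were also lower in 1-cell embryos than in oocytes. Of 14 stress genes, 2 were lower, also when adjusted over the list alone: the chaperone hsp-1 (F26D10.3), which went from 3279 ± 235.5 to 295 ± 85.9 RPKM (log2 -3.50), and hsp-110 (C30C11.4; -2.24). The list had an adjusted p of 0.0365 (adjusted p = 0.847 with an estimated correlation), of 0.0717 with libraries scaled to a common sum, of 0.0540 with quantile normalization and of 0.356 with the length trend removed. Of 19 cuticle and hypodermis markers, 4 were lower, also when adjusted over the list alone, among them the collagens col-140 (F26F12.1; 4.30 ± 3.12 to 0.101 ± 0.143 RPKM) and col-119 (C53B4.5; 2.86 ± 2.21 to 0.0140 ± 0.0198 RPKM). The list had an adjusted p of 0.00373 (adjusted p = 0.847 with an estimated correlation) and of 0.0581 with median-of-ratios scaling. Calls of col-140 and col-119 ended with a pseudocount of 5, without the filter on low values and with only the compared groups. Median-of-ratios scaling also ended that of col-119. None of 18 body wall muscle, 13 intestine, 7 somatic gonad or 4 yolk genes was called in this comparison, and their list tests had adjusted p of 0.259, 0.0671, 0.875 and 0.0928. The intestine list passed as lower with quantile normalization (0.0465) and with the length trend removed (0.0134). The yolk protein vit-2 (C42D8.2) had 1.08 ± 0.04 RPKM in oocytes and 0.0745 ± 0.105 in 1-cell embryos (adjusted p = 0.634). Among 14 neuron markers 1 was higher and 1 lower (adjusted p = 0.318), and the higher one, unc-119 (M142.1), stood at 26.8 ± 2.68 RPKM in oocytes and 194 ± 14.4 in 1-cell embryos. Its call ended with quantile normalization. As for oma-1, labels and protocol name different strains for the oocytes, so for unc-119 strain cannot be separated from stage.

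Some transcripts of sperm genes were higher in 1-cell embryos than in oocytes, while neither sperm list passed. ssp-16 (T27A3.3), a sperm-specific gene, went from 0.702 ± 0.669 to 42.8 ± 3.45 RPKM (log2 4.74, SE 0.47, adjusted p = 0.00566) and stood at 2068 ± 123.7 RPKM in sperm. The log2 change was 3.94 for msd-4 (C35D10.11), a gene of a major sperm protein domain family, 4.20 for msrp-2 (ZK484.5) and 2.01 for gsp-3 (W09C3.6), a phosphatase of sperm. The isoprenylcysteine methyltransferase gene icmt-1 (F21F3.3) changed by 4.18. Of 36 genes for spermatogenesis and sperm function, 6 were higher and 1 lower (5 and 1 adjusted over the list alone), and the list test did not pass (adjusted p = 0.392). The higher ones included spe-11 (F48C1.7; 1.83), fog-3 (C03C11.2; 2.33) and spe-36 (F40F11.4; 2.96), and the lower one was cpb-1 (C40H1.1; -1.43). Of 30 major sperm protein genes 2 were higher (0 adjusted over the list alone; list adjusted p = 0.134), msp-142 (K05F1.2; 1.42) and msp-40 (C33F10.9; 1.62). With the length trend removed that list was lower (adjusted p = 1.63e-04), with 0 members called. The removal corrected genes far higher in sperm at their mean level over all 8 libraries. An effect of the removal itself cannot be told apart here from a change of these genes. The members of that family are nearly identical in sequence, so reads cannot be assigned to them with certainty. The calls of spe-11, fog-3, spe-36, cpb-1, msp-142 and msp-40 ended with the length trend removed, and all of these except cpb-1 lost theirs under at least 1 other scaling.

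Ribosomal protein transcripts were higher as a list, a call that ended with the length trend removed. Of 75 cytosolic ribosomal protein genes, 26 were higher and 0 lower (30 and 0 adjusted over the list alone). rps-17 (T08B2.10) went from 147 ± 44.4 to 863 ± 232 RPKM (log2 2.55) and rpl-38 (C06B8.8) from 185 ± 29.6 to 859 ± 416 RPKM (log2 2.13). rps-23 (F28D1.7) had a log2 change of 1.92 and rpl-29 (B0513.3) of 2.45. The list had a median transcript length of 534 nucleotides and an adjusted p of 0.00205 (adjusted p = 0.900 with an estimated correlation). With the length trend removed its adjusted p was 0.833, on the lower side, with 3 members called, and rps-17 kept its call while rpl-38 (1.00), rps-23 and rpl-29 lost theirs. Of 57 histone genes, also with nearly identical members and a median length of 384 nucleotides, 8 were higher (8 adjusted over the list alone; list adjusted p = 0.145), including his-74 (W05B10.1; 740.2 ± 70.2 to 2702 ± 64 RPKM), whose call ended with quantile normalization.

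Germline and early zygotic groups with higher members did not pass as lists on the values as deposited. Of 34 genes for meiotic chromosomes, 8 were higher, also when adjusted over the list alone (list adjusted p = 0.0542, and 0.00187 with the length trend removed), including the recombination genes spo-11 (T05E11.4; 14.9 ± 2.83 to 80.4 ± 49.3 RPKM) and him-5 (D1086.4; log2 2.08). Of 39 Argonaute and small RNA pathway genes, 7 were higher and 2 lower, also when adjusted over the list alone (list adjusted p = 0.907), including mut-2 (K04F10.6; 2.18) and eri-1 (T07A9.5; 1.89). With the length trend removed, 15 of these were higher and 0 lower (adjusted p = 0.00645). Of 22 early zygotic transcripts, 6 were higher and 1 lower, also when adjusted over the list alone (list adjusted p = 0.0729, and 0.0488 with libraries scaled to a common sum). pgl-2 (B0523.3; 7.68 ± 0.36 to 36.3 ± 8.31 RPKM), pes-1 (T28H11.4; 1.81) and vet-2 (C35E7.1; 1.82) were among the higher ones, and the zinc finger gene die-1 (C18D1.1; -2.04) was the lower one. Single calls in this paragraph ended under at least 1 other scaling for spo-11, mut-2, eri-1 and vet-2, and with the length trend removed for die-1.

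mRNA decay, respiratory chain and translation factor lists held members that moved in both directions. Of 37 mRNA decay genes, 10 were higher and 5 lower (10 and 6 adjusted over the list alone; list adjusted p = 0.30), with lsm-7 (ZK593.7) at a log2 change of 2.30. Of 42 nuclear-encoded respiratory chain genes, 11 were higher and 5 lower (13 and 6 adjusted over the list alone; list adjusted p = 0.662), with cox-6A (F54D8.2) at 1.51 and the ATP synthase gene atp-1 (H28O16.1) at -2.90. Of 37 translation factors, 4 were higher and 4 lower (4 and 4 adjusted over the list alone; list adjusted p = 0.416), with the germline initiation factor iff-1 (T05G5.10; 380 ± 49.2 to 1878 ± 229 RPKM) at 2.30 and the elongation factor eef-2 (F25H5.4) at -1.74. The medians of these lists, 0.28, 0.45 and 0.45, were above 0 while their tests, which compare a list with all other genes, pointed lower. With the length trend removed lsm-7, cox-6A and atp-1 lost their calls, and eef-2 changed direction (0.33, adjusted p = 0.615).

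In total 2033 genes were higher and 707 lower in 1-cell embryos than in oocytes at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, by limma's moderated test on 11935 genes. The balance depended on scale: it was 988 higher and 968 lower with libraries scaled to a common sum, 841 and 1082 with median-of-ratios scaling, and 554 and 884 with quantile normalization. These scalings moved the median of all genes by -0.18, -0.24 and -0.30 from 0.35, and 498 and 638 genes were called in the same direction under all of these. Without either oocyte library 0 genes were higher and 6 lower, without 1-cell replicate 1 the counts were 1227 and 444, without 1-cell replicate 2 they were 1450 and 459, and with the length trend removed 1387 and 341. Of the 66 named genes that were called, 37 stayed called without the filter on low values, 2 stayed called without oocyte replicate 1, and 2 without oocyte replicate 2, 45 without 1-cell replicate 1 and 43 without 1-cell replicate 2, and none of these settings changed a direction.

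The comparison of 2-cell with 1-cell embryos asks what changes at the first division. The early zygotic list was higher and the eggshell list lower than other genes, and few single genes were called. The only genes called were AH10.2, at 0.131 and 0.0578 RPKM in the 1-cell libraries and 4.04 and 3.86 in the 2-cell libraries (log2 2.18, SE 0.17), and F58E6.6, at 0.133 and 0 RPKM against 3.89 and 5.21 (log2 2.37, SE 0.20), each with an adjusted p of 0.0180. These 2 and the GATA factor genes med-1 and med-2, which specify mesoderm and endoderm, were chosen after their values were seen. med-1 (T24D3.1) had a mean of 0.139 ± 0.197 RPKM at the 1-cell and 2.33 ± 1.03 at the 2-cell stage, and med-2 (K04C2.6) of 0.139 ± 0.197 and 2.87 ± 0.49. Within replicate number 1 the 2-cell minus 1-cell log2 difference was 2.15 for AH10.2, 2.11 for F58E6.6, 1.02 for med-1 and 1.46 for med-2, and within number 2 it was 2.2, 2.64, 2.02 and 2.08. Both med genes were called adjusted over the list alone among the 22 early zygotic transcripts, and 0 over all genes tested. That list was higher at the 2-cell stage (adjusted p = 1.53e-04, and adjusted p = 0.847 with an estimated correlation), with 8 members higher and 1 lower within both numbers, beside 3971 higher and 2561 lower of all 11935 genes tested. Its most abundant members tbx-9 (T07C4.6; log2 -0.07) and lin-26 (F18A1.2; 0.22) did not pass the test. The early zygotic list was also written as a marker of older embryos. Since the collection of 2-cell embryos is not described, older embryos among them cannot be told apart from a change at the first division.

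The eggshell list was lower at the 2-cell than at the 1-cell stage (0 of 18 called, adjusted p = 4.23e-05, and adjusted p = 0.847 with an estimated correlation), with 14 members lower within both replicate numbers. cpg-2 had 655 ± 49.2 RPKM at the 1-cell and 315 ± 118.7 at the 2-cell stage (log2 -1.10), and within replicate numbers 1 and 2 its log2 difference was -0.79 and -1.42. For egg-1 these within-number values were -0.77 and -1.04, for rme-2 -0.63 and -1.11, for chs-1 -0.62 and -0.73, and for the RNA-binding regulator lin-41 -0.78 and -0.90. The maternal regulators as a list did not pass (adjusted p = 0.309), and the log2 difference was 0.49 for mex-3, 0.31 for both gld-1 and oma-1, 0.13 for mex-5, 0.17 for pos-1 and -0.05 for nos-2.

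Polarity, Argonaute and proteasome lists also passed at this step, without a called member. Polarity and early cell fate genes were higher (adjusted p = 0.00305, adjusted p = 0.847 with an estimated correlation), with 21 of 30 higher within both numbers and mom-2 (F38E1.7) at a log2 difference of 0.29. Argonaute and small RNA pathway genes were higher (adjusted p = 0.0456, adjusted p = 0.847 with an estimated correlation), with 22 of 39 higher within both numbers. Both calls ended with the length trend removed (adjusted p = 0.127 and 0.700), and that of the Argonaute list also with median-of-ratios scaling (0.0728) and quantile normalization (0.131). Proteasome subunits were lower (adjusted p = 0.00205, adjusted p = 0.859 with an estimated correlation), with 14 of 32 lower and 1 higher within both numbers, list medians of 0.05 within number 1 and -0.18 within number 2, and pas-5 (F25H2.9) at a log2 difference of -0.18. This call ended with quantile normalization (0.485), and without 1-cell replicate 2 the list pointed higher (0.194). Each of the other lists had an adjusted p of 0.0514 or more, but the histone list was lower without 2-cell replicate 1 (7.0e-13) and higher without 2-cell replicate 2 (3.75e-17), and the cuticle list was lower (0.0147) and higher (0.0263) in the same settings. The median of the histone list was 0.58 within replicate number 1 and -0.55 within number 2. The ribosomal protein list was closest to the threshold (adjusted p = 0.0514). It passed as lower with median-of-ratios scaling (0.0103), and the major sperm protein list passed as higher with the length trend removed (5.86e-07), although its median as deposited was 0.53 within replicate number 1 and -0.19 within number 2.

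By limma's test 2 genes were higher and 0 lower at the 2-cell than at the 1-cell stage. Of the 11935 genes tested, 78 had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give. The fit was thus strict here, and its few calls do not show that little changed. With replicate blocks added after the data were seen, 883 genes (compared groups) and 1233 genes (embryo libraries) had such a p. Of these, 0 and 3 were called higher. The 2 calls ended without 1-cell replicate 1, 1-cell replicate 2, 2-cell replicate 2 or either oocyte library. No gene was called with median-of-ratios scaling, quantile normalization, a pseudocount of 5, a filter of 5 RPKM, no variance trend or only the compared groups. Differences of at least 1 log2 within both replicate numbers were seen in 17 genes that were higher and 8 that were lower, where 0.378 and 0.0692 would be shared if the numbers were independent, and in 1 gene with opposite signs.

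The comparison of 2-cell embryos with oocytes spans both steps. Of the eggshell list, 10 of 18 members were lower and 1 higher (12 and 1 adjusted over the list alone; list adjusted p = 1.12e-09, and adjusted p = 0.847 with an estimated correlation). cpg-2 had a log2 change of -4.59, cpg-3 (R06C7.4) of -4.30, cpg-1 of -4.24, egg-1 of -5.22, rme-2 of -5.05, cbd-1 of -3.47 and chs-1 of -2.86. Of 30 maternal RNA-binding regulators, 11 were lower, also when adjusted over the list alone (adjusted p = 4.16e-10, and adjusted p = 0.847 with an estimated correlation), including lin-41 (-4.90), puf-3 (-3.04), car-1 (-2.98), gld-1 (-2.37), mex-3 (-2.35) and mex-5 (-2.24). oma-1 did not pass here (-1.16, adjusted p = 0.0753). Both lists stayed lower with the length trend removed (adjusted p = 6.46e-08 and 8.15e-05), with 7 eggshell genes lower and, of the regulators, 3 lower and 1 higher. The calls of cbd-1 (-1.32), chs-1 (-1.68), puf-3 (-2.30), gld-1 (-1.16), mex-3 (-1.31) and mex-5 (-0.80) ended there, and those of puf-3 and mex-3 also with quantile normalization. Among the 10 largest decreases were again gfat-2 (860.0 ± 317 to 2.88 ± 1.23 RPKM, log2 -7.78), pygl-1 (-7.36), tsn-1 (-6.78) and gfat-1 (-5.80), with the UDP-glucose dehydrogenase sqv-4 (F29F11.1) at -5.16. Of 22 early zygotic transcripts, 10 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.00575, and adjusted p = 0.847 with an estimated correlation), among them pgl-2 (2.08), pes-1 (1.88) and ref-1 (T01E8.2; 1.70). The calls of pes-1 and ref-1 ended with median-of-ratios scaling. The sperm genes ssp-16 (3.98), gsp-3 (2.63) and spe-11 (2.03) were higher than in oocytes, but the spermatogenesis list did not pass (6 of 36 higher and 1 lower, adjusted p = 0.394). The call of spe-11 ended with median-of-ratios scaling and with the length trend removed. Among the 10 largest increases, some of them in genes without a match in the annotation, were F59C12.4 (3.58 ± 0.46 to 126 ± 79.3 RPKM, log2 4.64), msrp-2 (4.39), T05G5.1 (4.35) and the Skp1-related skr-8 (C52D10.9; 4.02).

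Most other list calls at the 2-cell stage matched in direction those at the 1-cell stage. Ribosomal protein genes were higher (23 of 75, 30 adjusted over the list alone, adjusted p = 0.00456), as were major sperm protein genes (5 of 30, 2 adjusted over the list alone, adjusted p = 0.0455). Polarity genes (5 of 30, 3 adjusted over the list alone, adjusted p = 5.62e-05), P granule genes (3 of 18, 1 adjusted over the list alone, adjusted p = 8.22e-04) and proteasome subunits (4 of 32, 3 adjusted over the list alone, adjusted p = 0.00198) were lower. Cell cycle genes (6 lower and 2 higher of 54, 5 and 2 adjusted over the list alone, adjusted p = 0.00280), cuticle markers (4 of 19, 5 adjusted over the list alone, adjusted p = 0.00220), stress genes (2 of 14, 2 adjusted over the list alone, adjusted p = 0.0335) and intestine markers (0 of 13, adjusted p = 0.0398) were lower too. With an estimated correlation each of these lists had an adjusted p of 0.847 to 0.900. The stress list had a median of 0.08 and a mean of -0.32. With the length trend removed the calls of the polarity (0.0748, 3 members higher and 3 lower), P granule (0.296), proteasome (0.297), cell cycle (0.740), stress (0.291) and ribosomal (0.825) lists ended, and the major sperm protein list pointed lower (0.0378). Median-of-ratios scaling ended the calls of the cuticle (0.0599), ribosomal (0.0552) and intestine (0.207) lists. Scaling to a common sum ended those of the stress (0.0632) and intestine (0.0657) lists, and quantile normalization those of the stress (0.0593) and major sperm protein (0.124) lists. Every other list had an adjusted p of 0.0654 or more in this comparison, but Argonaute genes (17 higher and 0 lower of 39, adjusted p = 0.00410) and meiotic genes (11 higher and 0 lower of 34, adjusted p = 0.00788) passed as higher at the preset correlation once the length trend was removed, where an estimated one was not run.

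In total 1960 genes were higher and 617 lower in 2-cell embryos than in oocytes. The counts were 1046 and 748 with libraries scaled to a common sum, 549 and 982 with median-of-ratios scaling, and 457 and 828 with quantile normalization. These scalings moved the median of all genes by -0.16, -0.31 and -0.37 from 0.42, and 387 and 562 genes were called under all. They were 0 and 11 without oocyte replicate 1, 0 and 7 without oocyte replicate 2, 595 and 262 without 2-cell replicate 1, and 185 and 118 without 2-cell replicate 2.

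The comparison of sperm with oocytes sets the gametes side by side. Sperm held the transcripts of its own machinery at levels far above those in oocytes. msp-56 (K07F5.3), a gene for the major sperm protein that drives sperm crawling, had 12239 ± 2137 RPKM in sperm and 0.507 ± 0.645 in oocytes (log2 13.05, SE 0.45, adjusted p = 1.06e-06), and all 30 genes of that family were higher (30 adjusted over the list alone; list adjusted p = 1.57e-14). Of 36 spermatogenesis and sperm function genes, 33 were higher (34 adjusted over the list alone; list adjusted p = 6.67e-10), including ssp-10 (K07F5.9; log2 11.59), ssp-16 (10.30), gsp-3 (9.87), spe-11 (8.99) and the sperm surface receptor gene spe-9 (C17D12.6; 5.08). The Argonaute genes alg-4 (ZK757.3; 8.21) and alg-3 (T22B3.2; 7.98), the histone gene his-70 (E03A3.4; 7.19) and the testis-type cytochrome c gene cyc-2.2 (ZC116.2; 9.76) were also higher, although the Argonaute list as a whole had 15 members higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.941). Ribosomal protein genes were higher in 73 of 75 cases (73 adjusted over the list alone; adjusted p = 9.06e-10), with rpl-10 (F10B5.1) at 2771 ± 1038 RPKM in sperm and 431 ± 97.6 in oocytes. Of these, 45 were higher and 2 lower with the length trend removed, and the list median went from 3.22 to 1.71 (adjusted p = 3.28e-04). With an estimated correlation these 3 called lists had an adjusted p of 0.847. The sperm libraries also held somatic transcripts, as described below, and which cells the ribosomal transcripts came from was not tested.

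Oocytes held the maternal program. The lectin gene clec-87 (C25A1.8) had 6695 ± 1376 RPKM in oocytes and 89.8 ± 113 in sperm (log2 -7.26, SE 1.06, adjusted p = 5.32e-04), and cpg-3 (-7.19), the protease gene try-1 (ZK546.15; -6.53) and the germline determinant meg-1 (K02B9.1; -6.51) were lower in sperm by similar amounts. Of 30 maternal RNA-binding regulators, 24 were lower and 1 higher, also when adjusted over the list alone (adjusted p = 7.89e-07), with oma-2 at -6.20, puf-5 at -6.17 and pos-1 at -5.79. Of 18 eggshell genes, 15 were lower and 1 higher (15 and 2 adjusted over the list alone; adjusted p = 2.81e-04), with cpg-2 at -6.12, egg-1 at -5.79 and rme-2 at -5.14. Lower lists also included proteasome subunits (26 of 32, adjusted p = 7.89e-07; pbs-2, C47B2.4, at -2.82) and polarity genes (18 of 30, adjusted p = 0.00109; mom-2 at -4.23 and apx-1, K08D9.3, at -3.81). mRNA decay genes (20 of 37, adjusted p = 0.00205; patr-1, F43G6.9, at -3.42 and ccf-1, Y56A3A.20, at -2.84) and histones (11 of 57, adjusted p = 0.00300; his-72, Y49E10.6, at -2.61) were lower too, as were cell cycle genes (19 of 54, adjusted p = 0.00886; cyb-3, T06E6.2, at -5.47 and plk-1, C14B9.4, at -2.43). The last lower lists were P granule genes (9 of 18, adjusted p = 0.0115), translation factors (13 of 37, adjusted p = 0.0208) and respiratory chain genes (6 of 42, adjusted p = 0.0456). Members higher in sperm numbered 1 in each of the proteasome, polarity and P granule lists, 2 histones, 3 mRNA decay genes, 5 cell cycle genes, 4 translation factors and 3 respiratory chain genes. Adjusted over the list alone the numbers lower were the same except for histones (10), cell cycle genes (18) and respiratory chain genes (4). With an estimated correlation the adjusted p of these lists was 0.847 to 0.900. Quantile normalization ended the calls of the mRNA decay (0.0593), cell cycle (0.516), P granule (0.148), translation factor (0.405) and respiratory chain (0.463) lists. Median-of-ratios scaling ended those of the translation factor (0.121) and respiratory chain (0.501) lists. These 2 lists had an adjusted p of 0.0584 each with the length trend removed, where 28 histones and 11 respiratory chain genes were lower.

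The sperm libraries also held transcripts of somatic tissues. Of 18 body wall muscle markers, 15 were higher than in oocytes and 2 lower, also when adjusted over the list alone (adjusted p = 0.00300, and adjusted p = 0.847 with an estimated correlation). The muscle troponin gene pat-10 (F54C1.7) had 412 and 2804 RPKM in sperm replicates 1 and 2 and 2.71 ± 1.06 in oocytes, and the actin gene act-4 (M03F4.2) had 1121 and 1166 in sperm and 25.9 ± 7.84 in oocytes. Of 13 intestine markers, 12 were higher, also when adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.847 with an estimated correlation), with the protease genes asp-1 (Y39B6A.20) at 374 and 72.9 RPKM and cpr-1 (C52E4.1) at 213 and 25.7. Lists that did not pass were cuticle markers (11 higher and 1 lower of 19, adjusted p = 0.122; col-119 at 426 ± 190 RPKM in sperm), somatic gonad markers (4 of 7 higher, adjusted p = 0.318; inx-8, ZK792.2, at 26.8 ± 1.5), and neuron markers (8 higher and 2 lower of 14, adjusted p = 0.30). Stress genes (7 higher and 3 lower of 14, adjusted p = 0.807), yolk genes (0 of 4, adjusted p = 0.743), meiotic genes (5 higher and 5 lower of 34, adjusted p = 0.464) and early zygotic transcripts (2 higher and 6 lower of 22, adjusted p = 0.189, and 0.0312 with quantile normalization) did not pass either. Adjusted over the list alone the counts were the same except for neuron markers (3 lower), stress genes (8 higher) and meiotic genes (1 higher and 0 lower). The yolk gene vit-2 had 45 RPKM in sperm replicate 1 and 1.00 in replicate 2. In total 4375 genes were higher and 2938 lower in sperm, against 4054 and 4020 with libraries scaled to a common sum, 5263 and 1929 with median-of-ratios scaling and 2807 and 4702 with quantile normalization. These scalings moved the median of all genes by -0.39, 0.61 and -0.81 from 0.16, and 2661 and 1929 genes were called under all.

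Whether transcripts that sperm holds and oocytes lack are seen in the zygote was tested on 1835 genes with at least 10 RPKM in both sperm libraries and at least 10-fold more than in oocyte replicate 1. In 1-cell embryos the median of the set was 0.30 log2 above oocyte replicate 2 (0.34 and 0.22 in the 1-cell libraries, SD 0.08, n = 2), and 1503 of the genes lay above that library. The gene test called 160 of the 1835 higher in 1-cell embryos than in oocytes, a smaller share than the 2033 of all 11935 genes tested. The set stood at percentile 100 of 10000 random lists matched on oocyte level, whose median was 0.05 and whose highest was 0.07. Those lists also held genes too low to be tested in any comparison, so they do not match the set on expression. The levels were low: the median RPKM of the set was 72 in sperm, 0.359 in 1-cell embryos, 0.435 in 2-cell embryos and 0.0544 in oocytes. At least 1 RPKM in both 1-cell libraries was found for 397 of the genes and at least 5 RPKM for 91. As a share of the sperm level, 1-cell embryos held 2.07% of ssp-16, 0.446% of msd-4, 0.467% of spe-11, 0.356% of gsp-3, 0.0779% of msp-142, 0.0314% of ssp-10 and 0.0127% of msp-56, each a mean of the 1-cell libraries. The share was 0.197% and 0.00230% in 1-cell replicates 1 and 2 for the muscle myosin gene unc-54, and 0.204% and 0.0348% for the muscle paramyosin gene unc-15. The 28 members of the spermatogenesis list in the set had a median of 0.33 (percentile 99.92), the 10 muscle markers of 0.17 (percentile 20.03) and the 5 intestine markers of -0.65 (percentile 0.05), comparisons chosen after the data were seen. The median of the set was 0.17 with median-of-ratios scaling, and 1.28 and 0.07 with a pseudocount of 0.1 and of 5.

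**Figure D3:**
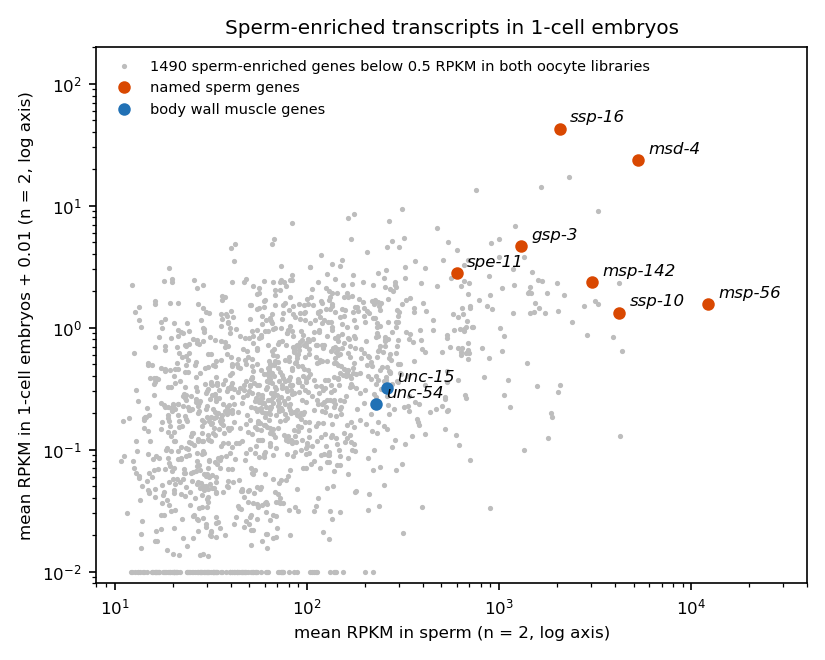
Mean RPKM + 0.01 in 1-cell embryos (vertical, log axis) against mean RPKM in sperm (horizontal, log axis), each over 2 libraries, with a point for each of 1490 genes of the sperm-enriched set below 0.5 RPKM in both oocyte libraries and coloured points for named genes. ssp-16 stood at 42.8 RPKM in 1-cell embryos and 2068 in sperm, and msp-56 at 1.56 and 12239.

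Whether changes between oocyte and 1-cell embryo continue or turn at the 2-cell stage was asked of the 2740 genes called at the first step. None of these was called at the second, in the same or the opposite direction, where independent lists would share 0.459 genes. Only 2 genes were called at the second step at all, so this overlap cannot answer the question. Genes lower at the 1-cell stage in the libraries numbered 1 were lower again at the 2-cell stage in the libraries numbered 2 in 28.8% of 1062 cases, with a median log2 difference of 0.16, and the reverse choice gave 29.1% of 1325 cases and 0.13. This split was chosen after the data were seen. Restricted to a mean of at least 10 RPKM the shares were 28.9% and 28%, against 48.1% and 35.9% of the genes that had changed in neither direction. Genes higher at the first step, under the same restriction, were lower at the second in 48.8% of 2406 and 61.9% of 2023 cases. The split was neither matched on transcript length nor run with the length trend removed. For genes of up to 500 nucleotides the medians were 1.43 at the first step and -0.06 at the second. For those of 2000 to 4000 nucleotides they were -0.17 and 0.17, so a turn cannot be told apart from the length trends. Across genes the correlation of the 2 steps was -0.255, where simulation without any effect gave -0.350 with noise shared by replicate number and -0.694 with independent noise, because both steps use the 1-cell libraries. The covariance was -0.0713, against -0.0230 and -0.155 in these simulations.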

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

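Settings named as added here (replicate blocks limited to some groups, calls shared by all scalings, length trend removed, subsets of the sperm set) were chosen after seeing the data. Where no cause is given, the cause was not tested. Genes higher in 1-cell embryos than in oocytes were 1034 without a filter, 988, 841 and 554 with a common sum, median-of-ratios and quantile scaling, 498 called under all scalings (added), 0 with a replicate block on the compared groups and 3340 with 1 on the embryo libraries (both added). Genes lower were 420 without a filter, 1082 with median-of-ratios scaling, 0 and 1110 with those blocks, and 341 with the length trend removed (added). Genes higher at the 2-cell than at the 1-cell stage were 0 with a pseudocount of 5, a filter of 5 RPKM, median-of-ratios or quantile scaling, only the compared groups, no variance trend, a block on the compared groups or all scalings together, 1 without a filter, and 6 with a common sum or the length trend removed. With the block on the embryo libraries they were 3. Genes higher in 2-cell embryos than in oocytes were 892 without a filter, 1046, 549 and 457 with those scalings, 387 under all, and 3446 with the embryo block. Genes lower were 330, 982 with median-of-ratios scaling, 395 and 977 with the blocks on the compared groups and on the embryos, and 310 with the length trend removed. Genes higher in sperm were 2890 with a filter of 5 RPKM, which tests fewer genes, 2807 with quantile scaling and 2661 under all, and genes lower were 1929, 4702 and 1929 with median-of-ratios, quantile and all scalings. Leaving out single libraries, which assumes that a lone library varies like the other groups, gave 0 to 1922 higher and 6 to 734 lower genes for 1-cell embryos, 0 to 2 higher for 2-cell against 1-cell embryos, and 0 to 2321 higher and 7 to 650 lower for 2-cell embryos against oocytes. These fits have fewer samples. Of the gene list tests, 41 passed at the preset correlation and 0 with an estimated one. Lists that turned with the length trend removed were ribosomal proteins (adjusted p = 0.833 in 1-cell and 0.825 in 2-cell embryos against oocytes, lower), major sperm proteins (1.63e-04 and 0.0378, lower) and proteasome subunits (0.932 in 1-cell embryos, higher). At the 2-cell against the 1-cell stage proteasome subunits turned without 1-cell replicate 2 (0.194, higher), histones without 2-cell replicate 1 (7.0e-13, lower) and cuticle markers without 2-cell replicate 2 (0.0263, higher). Without any other library these adjusted p ran from 1.68e-07 to 0.875 for proteasome subunits, from 3.75e-17 to 0.962 for histones and from 0.0147 to 0.793 for cuticle markers. The median of the sperm-enriched set was 1.28 and 0.0714 with pseudocounts of 0.1 and 5, 0.17 with median-of-ratios scaling, 0.76 for a sperm level of at least 100 RPKM, 0.17 for muscle markers and -0.65 for intestine markers (both added). An oocyte library could not be left out of it, since 1 chooses the set and the other measures it. Without a filter on low values 37 of 66 called named genes stayed called in 1-cell and 30 of 42 in 2-cell embryos against oocytes, and 45 of 46 in sperm. Of single named genes eef-2 turned (0.33) with the length trend removed. In all, 5110 other values for lists and genes kept their side of the threshold, 674 were weaker and 90 stronger, and 159 counts and medians stayed within their limits. By the labels same-numbered libraries share only a number. Their deviations from the group means correlated at 0.877 between 1-cell and 2-cell embryos, so same-numbered embryo libraries were alike beyond their number. Between oocytes and 1-cell embryos these deviations correlated at -0.170. Genes with an unadjusted p under 0.05 between 2-cell and 1-cell embryos, 78 without a block, were 883 with a replicate block on the compared groups and 1233 with it on the embryo libraries, and with a block on all groups the ribosomal list (0.0374, lower) and the major sperm protein list (0.0388, higher) passed there. That block also let meiotic genes pass in 1-cell embryos and histones in 2-cell embryos against oocytes (0.0386 each, higher), and respiratory chain genes in sperm had an adjusted p of 0.0507 under it. Depth is unknown for the oocyte libraries, and no alternative tested it.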

Other observations

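All the tests of explanations in this part were chosen after the results were seen, except the comparison of the sperm-enriched set with random lists, whose bounds alone were set afterwards.

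Transcripts of sperm genes were still present at the 2-cell stage. ssp-16 had 26.96 ± 15.1 RPKM in 2-cell embryos against 42.8 ± 3.45 in 1-cell embryos, and gsp-3 had 7.90 ± 3.12 against 4.64 ± 0.13, and neither difference passed the test. The median of the sperm-enriched set above oocyte replicate 2 was 0.37 log2 in 2-cell embryos. Other transcripts seen in the embryo stages were those of F59C12.4, at 33.4 ± 11.3 RPKM in 1-cell and 126 ± 79.3 in 2-cell embryos, with a 2-cell minus 1-cell log2 difference of 1.42 within replicate number 1 and 2.11 within number 2.

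Short transcripts stood higher and long ones lower in embryos than in oocytes. With the length trend removed the maternal RNA-binding and eggshell lists stayed lower at the preset correlation, the only one run there. The median of the maternal list went from -1.79 to -0.84 log2 from that of all genes, and the eggshell median from -2.07 to -1.55. The remaining distances were smaller than the interquartile ranges of the members (1.79 and 1.77). Fewer members (4 in place of 14 and 3 in place of 8) were then called lower. These values do not settle whether the length trend was the whole source of the fall. For the ribosomal protein list the trend could account for the whole rise, since the list came to -0.0235 log2 from the median of all genes. Whether the trend came from how well each preparation recovered RNA by length cannot be told apart from a change in the embryo, because each stage was collected and handled in its own way, and replicates of an embryo stage differed in slope by at most 0.140 of the difference between stages. Changes of the poly(A) tail, which polyadenylated RNA selection would read as changes of level, and another way of making the oocyte columns, were not tested and stay open.

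Sperm-enriched transcripts stood higher in 1-cell embryos than in oocytes. The set lay at percentile 100 of random lists matched on oocyte level, and of lists matched on level and length (median 0.32 against 0.07). This argues against an equal lift of all low values. Both kinds of list were drawn from all genes of the table outside the set, including genes too low to be tested. Every gene of the set had at least 10 RPKM in sperm. A lift or a length trend limited to genes expressed in some library was therefore not tested. The major sperm protein list, however, pointed lower once the length trend was removed (adjusted p = 1.63e-04). That removal used mean levels over all 8 libraries, including sperm, so it cannot decide whether these transcripts rose or fell. A carry-over of sperm RNA in a single proportion was argued against only for the set as a whole. The 526 genes of the set measured had a mean of at least 100 RPKM in sperm and under 0.5 RPKM in both oocyte libraries. Their share of the sperm level found in 1-cell embryos spread 41.3-fold or more between the 10th and the 90th percentile. For 48 genes of at least 1000 RPKM it spread 22.4-fold or more. The ratio of the sperm replicates spread 2.21-fold, and simulated counting error at the rough depths gave a mean of 2.43-fold or less per library. Shares taken from separate sperm libraries had a Spearman's rho across genes of 0.793 and 0.753. The set also held markers of muscle and intestine, and oocyte levels of up to 0.5 RPKM could change low shares. A single proportion for the transcripts that sperm itself makes was therefore not tested. A candidate explanation that stays open is delivery by sperm with unequal survival of transcripts, and so is transcription in the embryo or in the germ line of its mother, none of which these data test.

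Oocyte transcripts were found in sperm replicate 1. Of 39 maternal and eggshell genes with at least 100 RPKM in oocytes, 100% were higher in sperm replicate 1 than in replicate 2, with a median of 9.53% against 2.81% of the oocyte level. This is consistent with RNA of oocytes or of a hermaphrodite germ line in that preparation, although 84.2% of 1386 other genes abundant in oocytes were also higher in replicate 1, by a median ratio of 1.62 against 3.48. vit-2 and vit-6, made in the hermaphrodite intestine, had 45 and 18 RPKM in replicate 1 and 1.00 and 1.06 in replicate 2. The males' own germ line, at different stages in the preparations, stays open as a source and was not tested.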
